A study of Mus musculus with 6 samples.

How the data were processed

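The series measured poly-A RNA in 6 libraries of the mouse neuroblastoma line M1, 3 with a doxycycline-induced non-targeting hairpin and 3 with a hairpin against Igf2bp1. Per the labels' protocols, 600 ng of total RNA entered mRNA purification, poly-A RNA was taken from 200 ng, libraries were made with a stranded mRNA kit, and paired reads of 53 cycles were run on a NovaSeq. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0, HTSeq and the genome build GRCm38. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here, so counts of overlapping and antisense genes are uncertain. The deposited table holds raw read counts per gene, not normalised, as its whole numbers and differing totals show, with 1 column per library. It has 43721 rows, of which 43629 are mouse gene IDs and 92 are spike-in sequences whose counts are 0 in all libraries. Columns were joined to samples by the library names in the labels. Gene symbols came from GENCODE release M21 on GRCm38 and matched 42462 IDs. The 1167 unmatched IDs held 0.155% of reads, and coordinates are from the same annotation.

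Counts were normalised by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, two-sided, without covariates, over the 13445 genes that filterByExpr kept at its defaults (a minimum count of 10 and a minimum total of 15). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. CPM values were computed here from the deposited counts with TMM factors. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 31 lists with 5 or more tested members. Camera with an estimated correlation and fry were the alternatives. Library totals were 30756389, 35373076 and 33385813 counts in shNT replicates 1 to 3 and 25119655, 34014482 and 27372822 counts in shIGF2BP1 replicates 1 to 3. A count of 3, the upper limit that a count of 0 allows, corresponds to 0.0848 to 0.119 CPM. The counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The common biological coefficient of variation was 0.29. No 2 libraries agreed within sampling noise, with chi-square values per gene of 47.8 to 253 over all pairs.

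The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Igf2bp1, then 15 fixed genes, then up to 10 genes with the largest rise and 10 with the largest fall past the threshold with a mean CPM of 5 or more and no overlap between groups, then up to 4 members of each described list with the smallest p. Genes named outside it are said to be so in the text, and some genes that the rule takes are not reported here. The alternatives were RLE size factors, library size only, no filter, a filter at mean CPM 5, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, and an adjusted p threshold of 0.01. An edgeR fit with 1 surrogate variable from sva 3.50.0 and edgeR's bias-adjusted quasi-likelihood were added after the data were seen. The alternative for normalised values was not run, since the table holds counts.

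The tests were tested on simulated data drawn from the means and dispersions of this comparison. In 13445 genes with 200 changed, edgeR recovered 35.8% of genes changed 2-fold, 88.1% of those changed 4-fold and 95.5% of those changed 16-fold, and 17 of its 163 calls were false. DESeq2 made 47 false calls of 199 and limma-voom 17 of 157. Camera with the preset correlation called 20 of 20 lists of 30 genes shifted 2-fold and 1 of 600 unchanged ones. Smaller shifts, camera with an estimated correlation and fry were not simulated. In the simulation genes were independent, unlike real genes.

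For the closing section, 7-base words were searched in the longest annotated 3' UTR, of at least 50 bases, of 11334 tested genes, and in the coding sequence of 11028 genes. For each of 16097 words the log2 fold changes of genes with and without it were compared by a linear model with log length and GC content and their squares, using Python with numpy. Genes without an annotated 3' UTR were not searched. The same was done for each of the 10 splits of the 6 libraries into 3 and 3.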

Results

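Poly-A RNA was sequenced from M1, a mouse neuroblastoma cell line, after 6 days of doxycycline at 4 to 6 µg/ml, which switched on a short hairpin RNA. The 6 libraries formed 2 groups of 3. One group carried a non-targeting hairpin (shNT) and the other a hairpin against Igf2bp1 (shIGF2BP1). The labels name no other hairpin against Igf2bp1. An effect of the hairpin therefore cannot be told apart from other differences between the cells of the 2 groups. The deposited table gave whole-number read counts per gene. Library totals ran from 25119655 counts for shIGF2BP1 replicate 1 to 35373076 for shNT replicate 2, and 13445 genes had enough counts to be tested. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these 6 samples, which may be technical. The series title places the study in the immune environment of neuroblastoma, and its design text names a single comparison, knockdown against control.

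Igf2bp1 mRNA was not lower in the libraries labelled shIGF2BP1. Igf2bp1 (ENSMUSG00000013415) encodes an RNA-binding protein that is mostly active in fetal tissue and in tumours, and lies on the minus strand of chromosome 11, from 95957163 to 96005940 in GRCm38. The 3 shNT libraries held 37, 175 and 201 Igf2bp1 counts, and the 3 libraries labelled shIGF2BP1 held 67, 35 and 311. Normalised expression was 4.15 ± 2.56 CPM in shNT and 4.96 ± 5.58 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each). The log2 fold change was 0.25 ± 0.79 (SE), with a 95% interval from -1.50 to 2.00 and an edgeR adjusted p of 0.966. Mean log2 CPM differed by -0.09, and a two-sided exact permutation test of it gave p = 0.9, where 3 against 3 libraries cannot give less than 0.1. The sign turned to -0.18 without shNT replicate 1 and to -1.24 without shIGF2BP1 replicate 3. The targeted transcript showed no clear fall, and the interval does not exclude one. Every direction below therefore compares the libraries labelled shIGF2BP1 with those labelled shNT, and not a measured loss of Igf2bp1.

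**Figure D1:**
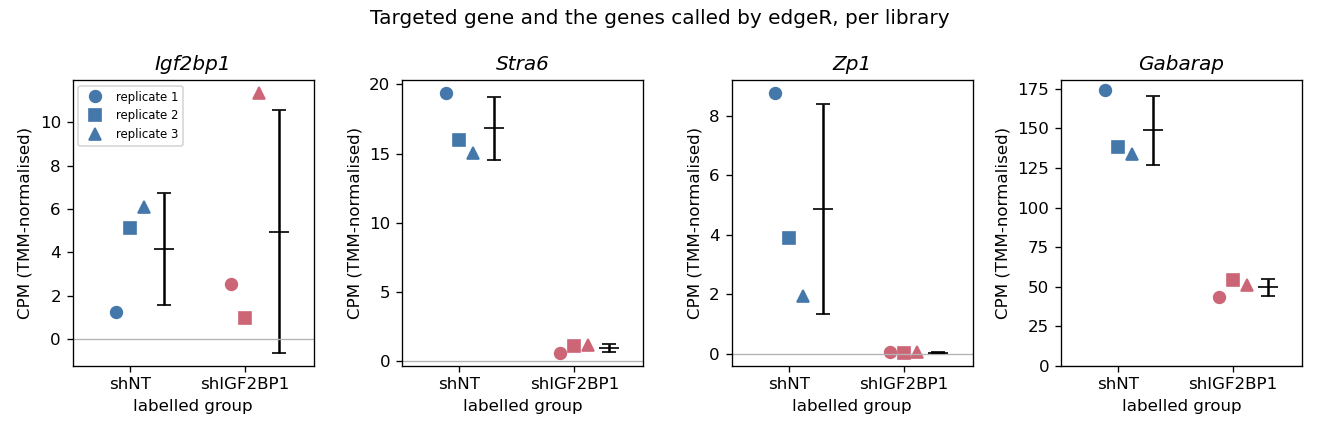
TMM-normalised CPM (y axis, linear, from 0 or just below) of Igf2bp1, Stra6, Zp1 and Gabarap in each library, by labelled group on the x axis, with symbols for replicates 1 to 3 and black bars for the mean ± SD (n = 3). Igf2bp1 overlaps between the groups, with its highest value, 11.3 CPM, in shIGF2BP1 replicate 3, while the other 3 genes lie lower in each library labelled shIGF2BP1 than in each shNT library.

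The edgeR test called 3 genes at an adjusted p under 0.05, and all 3 fell in the libraries labelled shIGF2BP1. Stra6 (ENSMUSG00000032327), the cell-surface receptor that takes up retinol from its carrier protein in blood, fell from 16.8 ± 2.27 to 0.949 ± 0.294 CPM (SD, n = 3 each), a log2 fold change of -4.13 ± 0.36 (SE) with an edgeR adjusted p of 0.00297. Gabarap (ENSMUSG00000018567), a ubiquitin-like protein of autophagosome membranes, fell from 149 ± 21.9 to 49.5 ± 5.61 CPM, a log2 fold change of -1.59 ± 0.20 with an edgeR adjusted p of 0.0354. Zp1 (ENSMUSG00000024734), known as a protein of the egg coat, was named after its values were seen, because its low mean expression put it outside the rule for named genes. It had 260, 132 and 64 counts in the shNT libraries and 1 count in each library labelled shIGF2BP1, a ratio of pooled normalised counts of 140 with a 95% counting interval from 47.5 to 679 (edgeR adjusted p = 0.0226). Without shNT replicate 1, which held 260 of the 456 shNT counts, the ratio was 86.5 with an interval from 29.2 to 423 (edgeR adjusted p = 0.0555). Stra6 lies on chromosome 9 from 58063788 to 58153996, Gabarap on chromosome 11 from 69991143 to 69994951 and Zp1 on chromosome 19 from 10914287 to 10920632. At an unadjusted p under 0.05 edgeR counted 962 genes, of which 426 were higher and 536 lower. DESeq2 called 82 genes (39 higher, 43 lower) and limma-voom 1. Without shNT replicate 3 edgeR called 5 genes, and without any other library it called 1, Stra6, with edgeR adjusted p values of 0.0163 to 0.0384.

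Of the genes that DESeq2 called and edgeR did not, 5 are named here after their values were seen. Txnip, an inhibitor of thioredoxin that responds to glucose, had 2527 ± 1190 CPM in shNT and 615 ± 255 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each; log2 fold change -2.04, edgeR adjusted p = 0.289). Etv1, an ETS-family transcription factor, had 3.42 ± 1.89 and 0.0554 ± 0.0547 CPM (edgeR adjusted p = 0.0648). Afp, the fetal serum protein alpha-fetoprotein, had 6.79 ± 1.99 and 24.3 ± 8.86 CPM (edgeR adjusted p = 0.183). Fhl1, a LIM-domain protein, had 2.11 ± 0.885 and 10.6 ± 0.72 CPM (edgeR adjusted p = 0.098). Col11a2, a fibrillar collagen chain, had 1.97 ± 0.656 and 16.8 ± 13.7 CPM (edgeR adjusted p = 0.21). Its log2 fold change of 3.1 became 2.26 without shIGF2BP1 replicate 2.

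Of 35 gene lists fixed before the data were examined, 31 had at least 5 tested members, and limma's camera with a preset correlation called 6 of them, 4 lower and 2 higher in the libraries labelled shIGF2BP1. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.933), and fry called 0 (smallest adjusted p = 0.90). No list had a member past an edgeR adjusted p of 0.05 over all genes tested. The integrated stress and unfolded protein response, the programme that slows translation and raises chaperone and amino acid genes, had 25 of 28 members with a negative log2 fold change and a median of -0.51 (camera adjusted p = 1.12e-07; adjusted p = 0.933 with an estimated correlation). Its median lay above 0.1 in each shNT library and below 0.1 in each library labelled shIGF2BP1, and 0 members were called when adjusted over the list alone. The amino acid transporter Slc7a5 had 424 ± 98.3 CPM in shNT and 193 ± 87.9 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each). Nupr1, a stress-induced chromatin protein, had 97 ± 38.5 and 40.1 ± 18.2 CPM, and Xbp1, the transcription factor activated by Ire1 splicing, had 197 ± 57.4 and 112 ± 19.4 CPM.

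Mesenchymal identity genes of neuroblastoma, the set that marks the less differentiated, migratory state, had 23 of 29 members with a negative log2 fold change and a median of -0.40 (camera adjusted p = 0.00153; adjusted p = 0.933 with an estimated correlation). Prrx1, a homeobox factor of that state, had 142 ± 10.4 CPM in shNT and 62.3 ± 11.6 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each; edgeR adjusted p = 0.13), and was the 1 member called when adjusted over the list alone. Fosl1, an AP-1 subunit, had 122 ± 137 and 32.7 ± 12.3 CPM. Its log2 fold change of -1.90 moved to -0.41 without shNT replicate 3. Collagens and extracellular matrix genes had 22 of 31 negative log2 fold changes, with a median of -0.36 (camera adjusted p = 0.00679; adjusted p = 0.933 with an estimated correlation), and 2 members were called when adjusted over the list alone. These 2 went in opposite directions. Thbs2, a matrix thrombospondin, had 145 ± 11.9 and 71.4 ± 17.3 CPM, and Col12a1, a fibril-associated collagen, had 0.0898 ± 0.10 and 0.711 ± 0.121 CPM. Col12a1 had 9 counts in shNT, 7 of them in replicate 2, and its pooled ratio of 7.74 (95% counting interval 3.83 to 17.7) became 22.6 without that library (6 to 191). The call on this list was lost without shNT replicate 2, shIGF2BP1 replicate 1 or shIGF2BP1 replicate 2, at camera adjusted p values of 0.11, 0.177 and 0.099, and with no filter on low counts (camera adjusted p = 0.144). Glycolysis and hypoxia genes had 26 of 32 negative log2 fold changes with a median of -0.30 (camera adjusted p = 0.00213; adjusted p = 0.956 with an estimated correlation). Ero1l, an oxidase of the endoplasmic reticulum, had 294 ± 106 and 172 ± 39.5 CPM, and P4ha1, a collagen prolyl hydroxylase subunit, had 242 ± 91.5 and 146 ± 41.7 CPM. That call was lost without shNT replicate 2 (camera adjusted p = 0.384) or shIGF2BP1 replicate 2 (camera adjusted p = 0.0992).

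Interferon-stimulated genes had 31 of 40 positive log2 fold changes with a median of 0.23 (camera adjusted p = 0.00105; adjusted p = 0.933 with an estimated correlation). Usp18, the protease that removes ISG15 and damps interferon signalling, had 0.278 ± 0.202 CPM in shNT and 2.33 ± 0.793 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each; log2 fold change 3.06 ± 0.63 SE, edgeR adjusted p = 0.284; 3.79 without shNT replicate 1), and was the 1 member called when adjusted over the list alone. Gbp7, a guanylate-binding protein, had 2.02 ± 0.748 and 6.09 ± 2.89 CPM, and Cmpk2, a mitochondrial nucleotide kinase, had 1.02 ± 0.64 and 3.17 ± 1.62 CPM. The Cmpk2 log2 fold change of 1.63 became 2.26 without shNT replicate 1 and 1.16 without shIGF2BP1 replicate 1. With only genes of mean CPM 5 or more, the list was no longer called (camera adjusted p = 0.459). Mitochondrially encoded transcripts had 11 of 13 positive log2 fold changes with a median of 0.33 (camera adjusted p = 0.0424; adjusted p = 0.956 with an estimated correlation), and took 2.21% to 3.69% of the counts of a library. That call was lost without shNT replicate 2 or 3 or shIGF2BP1 replicate 1 or 2, at camera adjusted p values of 0.124 to 0.454, and with no filter on low counts (camera adjusted p = 0.113).

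**Figure D2:**
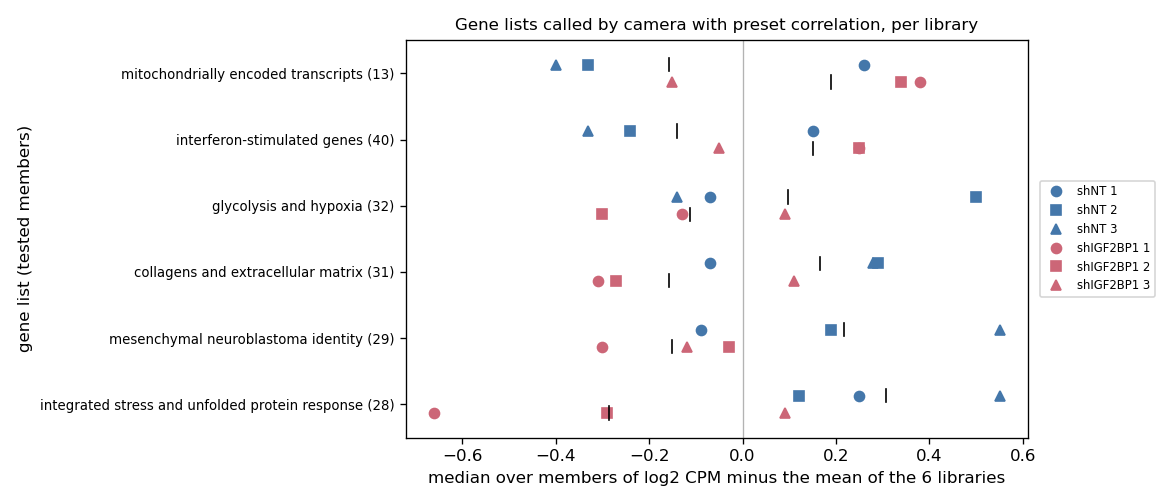
Median over the tested members of each list (y axis) of log2 CPM minus the mean of the 6 libraries (x axis), with a symbol per library and a black tick at each group's mean, for the 6 lists called by camera with a preset correlation. The 2 groups do not overlap for the integrated stress and unfolded protein response, while for the other 5 lists at least 1 library lies within the range of the other group.

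Antigen presentation and other immune genes named in advance did not pass the test. B2m, the invariant chain of MHC class I, had 720.1 ± 123 CPM in shNT and 628 ± 83.5 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each; edgeR adjusted p = 0.912). H2-D1, a class I heavy chain, had 123 ± 31.9 and 131 ± 48.9 CPM (edgeR adjusted p = 0.967), and shares sequence with other class I genes, so its counts are uncertain. Of 15 tested MHC class I members, 7 were higher and 8 lower (camera adjusted p = 0.78), and 0 were called when adjusted over the list alone. Cd274, which encodes the checkpoint ligand PD-L1, had 2.13 ± 0.394 and 2.47 ± 1.34 CPM (edgeR adjusted p = 0.953), and Cd276, a B7-family protein, had 103 ± 14.7 and 110.4 ± 5.64 CPM (edgeR adjusted p = 0.94). Chemokines and cytokines had 13 of 20 negative log2 fold changes (camera adjusted p = 0.569). Its members with the smallest p were the cytokine Mif, at 381 ± 89.8 and 249 ± 53.5 CPM (edgeR adjusted p = 0.684), and the secreted phosphoprotein Spp1, at 148 ± 65 and 90.9 ± 21.6 CPM (edgeR adjusted p = 0.695). The monocyte attractant Ccl2 had 4.87 ± 2.05 and 6.2 ± 0.384 CPM, and the neutrophil attractant Cxcl1 had 4.39 ± 1.3 and 7.47 ± 3.45 CPM. Csf1, the macrophage growth factor, had a log2 fold change of -0.51 ± 0.49 that became 0.52 without shNT replicate 3. B4galnt1, the enzyme that makes the ganglioside GD2, had a log2 fold change of -0.62 ± 0.26 (edgeR adjusted p = 0.686).

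Genes reported as IGF2BP1 mRNA targets showed no shared direction, with 8 of 23 tested members positive and 15 negative (camera adjusted p = 0.67). Mycn, the neuroblastoma oncogene, had 39.2 ± 11 CPM in shNT and 44.6 ± 5.85 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each; edgeR adjusted p = 0.918). Lin28b, which blocks let-7 maturation, had 13.3 ± 9.03 and 15.5 ± 5.00 CPM (edgeR adjusted p = 0.943), and the related Igf2bp2 had 4.33 ± 0.759 and 4.85 ± 1.57 CPM (edgeR adjusted p = 0.955). Myc had a log2 fold change of -2.88 ± 0.94 (edgeR adjusted p = 0.574), and 3996 counts in shNT replicate 3 against 83 to 372 in the other 5 libraries. Without that library its log2 fold change was -0.44. Igf2bp3 and H2-K1 had too few counts to be tested.

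Adrenergic identity is the sympathetic-like state of neuroblastoma. Th and Dbh, enzymes of catecholamine synthesis named after their values were seen, had 0 counts in each of the 6 libraries, while Hand2, a factor of sympathetic development, had 333 ± 127 CPM in shNT and 439 ± 15.6 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each). Of 31 adrenergic members, 9 had enough counts to be tested, so the result covers only part of the list. The tested members gave 4 positive and 5 negative log2 fold changes with a median of -0.05 (camera adjusted p = 0.885). The catecholamine enzyme Ddc was the 1 member called when adjusted over the list alone, with 0.149 ± 0.108 and 1.12 ± 0.508 CPM (log2 fold change 2.89, edgeR adjusted p = 0.431 over all genes; 3.59 without shNT replicate 1). Few markers of blood and vessel cells had enough counts to be tested. The leukocyte marker Ptprc and the glial factor Sox10, also named after their values were seen, were too low to test, and the lists of macrophage and leukocyte, endothelial and erythroid markers had 4, 3 and 0 tested members. Adjusted over the list alone, 2 macrophage and leukocyte markers, Cd68 and Fcer1g, were called in opposite directions, and 1 endothelial marker, Kdr, was called. Cd68, a lysosomal protein of macrophages that tumour cells also express, had 11.9 ± 3.6 and 4.12 ± 1.28 CPM (edgeR adjusted p = 0.403), and Fcer1g, a receptor subunit of myeloid cells, had 0.0688 ± 0.0942 and 0.438 ± 0.112 CPM (edgeR adjusted p = 0.616). The 7 shNT counts of Fcer1g included 6 in replicate 2, and its pooled ratio of 6.22 (95% counting interval 2.76 to 16.5) became 28.2 without that library (4.78 to 1140). Kdr, a vascular endothelial growth factor receptor, had 6.03 ± 3.81 and 1.55 ± 0.846 CPM (edgeR adjusted p = 0.524). Fibroblast markers gave 5 positive and 3 negative log2 fold changes of 8 (camera adjusted p = 0.909), and went both ways. Postn, a matrix protein with the smallest p of the list, had 0.119 ± 0.117 and 1.4 ± 1.67 CPM (log2 fold change 3.48 ± 1.08 SE, edgeR adjusted p = 0.537; 1.82 without shIGF2BP1 replicate 3), and Pdgfra, a growth factor receptor of mesenchymal cells, had 21.3 ± 7.93 and 13.2 ± 0.589 CPM. Schwann and glial markers gave 2 positive and 3 negative of 5 (camera adjusted p = 0.586).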

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

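The surrogate-variable and bias-adjusted fits, and the estimated correlation without a library or at mean CPM 5, were chosen after seeing the data. The count of 3 called genes stayed at 3 with RLE size factors or library size only and was 4 with the bias-adjusted fit. It was 138 without a filter (54 higher, 84 lower), 82 with DESeq2 (39 higher, 43 lower), 18 with the replicate block (6 higher, 12 lower), 6 with 1 surrogate variable, and 1 with the filter at mean CPM 5, with limma-voom or at an adjusted p of 0.01. Leaving out each library gave 1 to 5 calls. Stra6 was called in all 15 alternatives, with adjusted p values from 8.92e-30 with DESeq2 to 0.0384 with edgeR without shNT replicate 2. Gabarap lost its call in 7 of 15 alternatives and Zp1 in 6 of 14, both keeping their direction. Igf2bp1 turned to -0.047 with the replicate block and -0.24 with limma-voom, ran from -1.24 to 0.76 when libraries were left out, and was 1.16 with 1 surrogate variable. It was never called. The filter at mean CPM 5 removed Igf2bp1, Zp1 and other low genes, which have no value there. Same-numbered libraries had deviation correlations of 0.19, -0.09 and 0.28, against -0.37 to 0.22 for unlike numbers, and not every library correlated best with its own number. So few pairs cannot show whether the numbers pair the samples. Calls of fixed gene lists fell from 6 to 1 with 1 surrogate variable and 0 with fry or an estimated correlation, also without each library or at mean CPM 5, and were 4 to 9 when libraries were left out with the preset correlation. Immediate early genes and NF-kB targets passed with the replicate block (camera adjusted p = 0.0236 each) and with library size only (0.0311 and 0.0333).

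Some named genes that were not called changed sign. With 1 surrogate variable the log2 fold change was -0.009 for Mycn, -0.14 for H2-D1, 0.36 for Csf1 and 0.74 for Rn7sk. When libraries were left out, the values ran from -0.037 to 0.94 for Lin28b, -0.29 to 0.50 for Cd274, -0.006 to 0.20 for Cd276, -0.25 to 0.31 for H2-D1, -0.88 to 0.52 for Csf1, -1.41 to 0.15 for Gm42418 and -3.07 to 0.62 for Rn7sk. The changed signs of Csf1 and of Gm42418 and Rn7sk, named after their values were seen, came without shNT replicate 3. The causes were not tested. The median over all genes moved by at most 0.08 (log2) under any scaling. Depth limits Zp1, at 1 count per library labelled shIGF2BP1.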

Other observations

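The tests on Igf2bp1, shNT replicate 3, the count of called genes over splits, the estimated correlation without a library or at mean CPM 5, base composition and a single deciding library were chosen after the results were seen. Several other gene lists missed the threshold with all 6 libraries and passed it without 1 of them. S phase and E2F targets had 26 of 32 positive log2 fold changes (camera adjusted p = 0.569, and 6.2e-09 without shIGF2BP1 replicate 2). Their direction in camera with an estimated correlation turned to lower without shIGF2BP1 replicate 1 or 3. G2 and mitosis genes had 17 of 30 positive (camera adjusted p = 0.722, and 0.000259 without shNT replicate 2). These turned to lower without replicate 1 or 3 of either group. Cholesterol biosynthesis had 17 of 24 positive (camera adjusted p = 0.50), with 0.000236 without shNT replicate 2 and 0.0011 without shIGF2BP1 replicate 2. It turned to lower without replicate 3 of either group. Nuclear OXPHOS subunits had 22 of 31 positive (camera adjusted p = 0.132), with 0.000675 without shNT replicate 1, 0.0117 without shIGF2BP1 replicate 2 and 0.0412 at mean CPM 5 or more. They turned to lower without shNT replicate 3. The members of these 4 lists move together from library to library, with estimated correlations of 0.80, 0.706, 0.805 and 0.627, and with an estimated correlation each list had a camera adjusted p of 0.956. With an estimated correlation camera called 0 lists without any 1 library or at mean CPM 5 or more (smallest adjusted p = 0.415), so none of the calls above or of the lists that follow held.

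Heat shock genes had 10 of 10 positive log2 fold changes with a median of 0.17 (camera adjusted p = 0.0578), among them the co-chaperone Dnaja1 at 92.7 ± 20.9 CPM in shNT and 131 ± 17.4 CPM in the libraries labelled shIGF2BP1 (SD, n = 3 each). Their camera adjusted p was 0.0117 without shIGF2BP1 replicate 2 and 0.0318 at mean CPM 5 or more. Immediate early genes had 16 of 19 negative log2 fold changes with a median of -0.64 (camera adjusted p = 0.0578), and 6.16e-05 without shNT replicate 2, 0.0261 without shIGF2BP1 replicate 2 and 0.0286 at mean CPM 5 or more. NF-kB targets had 18 of 22 negative with a median of -0.51 (camera adjusted p = 0.0578), and 0.0323 without shNT replicate 1, 0.00156 without shNT replicate 2 and 0.0117 without shIGF2BP1 replicate 2. The lower direction of immediate early genes and NF-kB targets rested on shNT replicate 3. Relative to the mean of all libraries, their medians were 1.12 and 0.94 there, and at most 0.02 and 0.01 in any other library. Without it both turned higher (camera with an estimated correlation, unadjusted p = 0.925 and 0.782).

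The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The labelled split called 3 genes, the highest other split 2, and 1 of 10 splits reached the labelled count. For gene lists, the labelled split called 6 and the highest other split 11, and 9 of 10 splits called as many. The split of shNT replicate 1 with shIGF2BP1 replicates 1 and 2 against the rest, which exchanges shNT replicate 1 and shIGF2BP1 replicate 3, counted 1927 genes at an unadjusted p under 0.05, against 962 for the labelled split, which points to a structure of the samples that crosses the groups.

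Igf2bp1 was not lower in the libraries labelled shIGF2BP1. A swap of shNT replicate 1 and shIGF2BP1 replicate 3 stays open, since the evidence goes both ways: the labelled split had 8 genes with a gap of 4-fold or more (CPM plus 0.1), against 1 in the swapped split and at most 2 in any other, and with CPM plus 0.5, seen first, 2, 0 and 0, while the swapped split had 15 genes against 13 at 2-fold or more, 1927 against 962 at an unadjusted p under 0.05 and 11 called lists against 6. Too few reads is argued against, because the pooled ratio had a narrow 95% counting interval both with all libraries (1.09, from 0.948 to 1.25) and without shIGF2BP1 replicate 3, which held 311 of the 413 counts of its group (0.389, from 0.31 to 0.484; log2 fold change -1.24), so that the ratio rested on 1 library and the spread between libraries, not counting, set the limit. Igf2bp1 may follow a culture state that crosses the groups: over 6 libraries its log2 CPM had r = 0.73 with the first principal component of the other genes (exact permutation p = 0.0972; rho = 0.77, exact permutation p = 0.103; r = 0.75 without the 2 farthest libraries; 1 relation computed), which leaves this open. Protein was not analysed here, so an effect of the hairpin on translation is untested.

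shNT replicate 3 stood apart from the other 5 libraries, 2 of which share its group, so no biological explanation from the design was tested. Its Myc and Csf1 lay 4.18 and 1.75 above the mean of the others on the log2 scale, and, named like Lars2, Fos and Egr1 after their values were seen, Gm42418, a gene overlapping ribosomal RNA sequence, and the small nuclear RNA Rn7sk lay 2.21 and 4.18 above. Ribosomal and small nuclear RNA taking up counted reads is argued against as the cause of the gene shifts, since Gm42418, Rn7sk and Lars2 together took 0.48% of its counts. Reads not counted to a gene are not seen here, so the ribosomal RNA content of the library was not measured. Why Gm42418 and Rn7sk were higher there was not tested. An acute growth factor response in that culture may account for part of it and stays an open hypothesis. The median deviation of 19 immediate early genes was 1.34, at percentile 100 of 10000 random lists matched on expression. It was 1.24 for the 16 without Myc, Fos and Egr1, also at percentile 100. However, the list was tested after Myc and Egr1 had been seen high there, and Fos lay only 0.47 above. The random lists drew genes independently, while immediate early genes move together (estimated correlation 0.428). These percentiles therefore do not show how rare such a deviation is. A stress response stays open too, since the stress lists went both ways there: relative to the mean of the 6 libraries, heat shock genes had their lowest median of any library, -0.32, with Hspa8 at 290.1 CPM against 1097 to 1826 CPM in the other 5, while the integrated stress and unfolded protein response had its highest, 0.55, with Atf3, also on the immediate early list, at 54.8 CPM against 2.56 to 8.13 CPM, and Xbp1, Nupr1 and Slc7a5 highest there at 259, 134 and 537 CPM.

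Genes with the word ACCACCG in the 3' UTR lay lower in the libraries labelled shIGF2BP1, which may reflect a seed match of the induced hairpin, a hypothesis here because the hairpin sequence was not used. Of 16097 words this had the most negative t statistic, -6.17, against -4.58 as the most negative in any other split, where the same word gave it in a split that mixes the groups, and 70.8% of 301 genes with it had a negative log2 fold change against 51.6% of the others; the direction of the other splits is arbitrary, though, and with either sign the AU-rich word TATTTAT lay farther from 0 in 4 of those 9, at 6.25 to 8.73, so a value of that size alone is not rare. A test set before its result was seen took 929 genes with the word in the coding sequence and not in the 3' UTR. It used the fold changes of the same 6 libraries. The t statistic was -5.99, rank 2 of 16381 words, and the lowest word, CCACCGC at -6.12, overlaps ACCACCG. Over the other splits the coding sequence t statistic of ACCACCG ran from -4.03 to 2.8, although other words there reached 7.36. Its 3' UTR t statistic ran from -4.58 to 4.0 there. The 4.0 came from the split that exchanges shNT replicate 1 and shIGF2BP1 replicate 3. A structure of the samples that crosses the groups therefore stays open here too. The 3' UTR and coding sequence t statistics shared their sign in every split, also those that mix the groups. The coding sequence result is therefore not separate evidence for a seed match. Base composition of the 3' UTR stays open. The word was picked as the lowest, so the next word of the same bases with a CG step, at -4, had to lie closer to 0. A single deciding library is argued against by t statistics no closer to 0 than -5.12 when each library was left out. These fits share libraries with the fit that picked the word, so they do not test the difference anew. The word genes' mean relative to other genes was -0.022 in shNT replicate 1 and -0.032 in shIGF2BP1 replicate 3. It was 0.16 and 0.158 in shNT replicates 2 and 3, and -0.136 and -0.127 in shIGF2BP1 replicates 1 and 2. Those libraries carried most of the difference. Gabarap, Nsa2, Oaf, Lman2, Selenon and Sgms2, named after their values were seen, hold the word and have the smallest edgeR p of the genes that do. Their log2 fold changes were -1.59, -1.46, -1.41, -1.11, -0.90 and -1.07, and edgeR called Gabarap alone (adjusted p = 0.0354). At an edgeR unadjusted p under 0.05, 38 genes with the word were lower and 8 higher. Stra6 lacks the word, Zp1 was not searched, and Igf2bp1 itself holds it, with a log2 fold change of 0.25. Of the genes named from the integrated stress list, Slc7a5 holds it (log2 fold change -1.14), while Nupr1 and Xbp1 lack it.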
